A study of Escherichia coli K-12 with 36 samples.

How the data were processed

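RNA of Escherichia coli K-12 DHB4 was sequenced in 36 libraries, 12 groups of 3 replicates that combine 3 plasmids (empty vector, FevRCit, FevREco105) with 4 conditions. Overnight cultures were diluted 100-fold into 15 mL of medium, and 1.5 mL was harvested for RNA, whose integrity number was above 9, per the labels' protocols. The wild-type libraries at 30 °C were depleted of ribosomal RNA with a kit, made strand-specific with dUTP, and were prepared, sequenced and analysed by a separate provider, per the labels' protocols.

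The submitters' processing notes name Bowtie2 2.3.4.1, featureCounts, Subread 1.6.4 and DESeq2 1.28.1, without saying which step used which option. The genome build and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes cannot be separated with certainty. Per the file headers, each of the 8 tables holds 6 values for each gene. The signal the authors deposited is a mean normalised count over the libraries of the comparison. The fold change and its standard error are on the log2 scale, per the file headers. The Wald score that the authors deposited equals the log2 fold change divided by its standard error, which was checked in all 8 tables. The p-value and the adjusted p-value were deposited as the authors' DESeq2 test gave them, and a gene without an adjusted p-value was left out of counts. A combined table that repeats the fold changes and adjusted p-values of the 8 tables was not used, because it holds no standard errors or means. There are 0 columns of per-sample values that were left unused.

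The direction of the fold change was settled from the values. The empty-vector level implied by the mean and fold change should be the same in the tables of both homologs in a condition. Over genes whose fold changes differed by at least 1 on the log2 scale, the median deviation was at most 0.0015 when the regulator is the numerator and at least 0.081 when the empty vector is, so fold changes are regulator over empty vector. Gene symbols were matched to the RefSeq annotation of assembly ASM584v2, used for names and for which genes neighbour each other, with no coordinates taken. All 4462 symbols matched in 6 tables, and 4363 of 4419 in the tables of the wild type at 30 °C. Depth per library was not analysed. The summed mean normalised counts, a stand-in for it, were 19032303 and 19218367 in the wild type at 30 °C, 6369594 and 4833790 in the wild type grown at 42 °C, 3050801 and 2940890 in the degP deletion at 30 °C and 5962138 and 5187104 after the shift. At 30 °C in the degP deletion 941 and 1026 genes had no adjusted p-value, against 165 and 247 in the wild type at 30 °C.

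The planned test, a count model refitted to raw counts, needs counts per library. The plan, written before the data were examined, said that with fold changes alone the authors' values would be described without a test. The authors' calls at an adjusted p under 0.05 are therefore reported as such. The following steps were added after the tables were seen. The difference of 2 log2 fold changes was tested against the normal distribution, 2-sided, with the root of the summed squared standard errors, and adjusted by Benjamini-Hochberg over genes with an adjusted p in both tables. Between homologs the same empty-vector libraries enter both fold changes, so this error is too large. An alternative used the regulator libraries' part of the error alone, from the dispersion implied by the deposited standard error. A fold change is a ratio within its own table, so its difference needs no common scale of the tables. The 37 gene lists of regulons, pathways and complexes, fixed before the data were examined, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald scores. The preset inter-gene correlation was 0.01, lists needed at least 4 genes, and p-values were adjusted over the lists of a comparison. An estimated correlation needs values per library, so a preset correlation of 0.05 and a rank-based test stand in for it. Per list, the text counts members by the authors' adjusted p and by the p adjusted over the list alone.

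Unchanged groups were simulated 20 times per condition with negative binomial counts at the implied empty-vector means and dispersions, to give the covariance and correlation that shared controls produce. Overlaps of calls in these groups were not used, because the adjustment is built to give few calls where no gene changes. Genes are named by a rule fixed before the data were examined. Per comparison it takes up to 10 genes per direction with the largest fold changes, among those with adjusted p under 0.05, at least 2-fold change and a mean of at least 20 in the higher group. It adds up to 10 per direction that were called in all 4 conditions, up to 10 of the largest differences between homologs and up to 5 between temperatures, degP, and up to 4 members of each list that passed. The rule's condition on replicate values could not be applied. Genes outside the rule that are named for background (such as slyX and the neighbours of araC) were chosen after their values were seen.

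The steps were tried on simulated data with 200 changed genes per condition, with means and dispersions taken from the FevRCit comparisons alone. The authors' DESeq2 test was not rerun on them. A normal test stood in for it, with a standard error from the same dispersions that the counts were drawn with. The percentages below are therefore not those of the authors' calls, which may recover fewer genes. In the wild type at 30 °C the median implied dispersion was 0.00683 with FevRCit and 0.0166 with FevREco105. Recovery with FevREco105, and of homolog differences, may therefore be lower there than given. The difference between temperatures ran on 2984 genes in the degP deletion, 167 of them changed, and on 3579 in the wild type, 191 of them changed. In the wild type at 30 °C, with 3873 genes, the stand-in for the test against the empty vector recovered 93.0% of genes changed by 1 on the log2 scale. Of those changed by 2 it recovered 99.0%. In the degP deletion at 30 °C, with 3021 genes, it recovered 52.0% and 91.0%, and 7.59% of its calls were unchanged genes. The difference between homologs recovered 26.0% and 79.0% there. The difference between temperatures recovered 51.8% and 90.5% in the degP deletion, where 11.1% of calls were unchanged genes, and 86.5% and 94.7% in the wild type. A list of 20 genes shifted by 0.5 on the log2 scale gave p-values of 0.00118 or below in the 4 simulated conditions, and an unshifted list at least 0.47.

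Alternatives were an adjusted p under 0.01, a 2-fold minimum, no low-count filter (adjustment over all genes with a p-value), a mean of at least 20, recentring on the median fold change, and the list test settings. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.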

Results

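Total RNA was sequenced from Escherichia coli K-12 strain DHB4, a laboratory strain, that carried a plasmid for FevRCit, the same plasmid for FevREco105, or the empty vector. The sample titles name the constructs pAL-FevRCit-CYTO-FLAG and pAL-FevREco105-CYTO-FLAG. The amount of each protein was not analysed here, so differences between homologs cannot be told apart from differences in amount. FevRCit and FevREco105 are homologous transcription factors, and the series asks which genes each one changes in cells with and without DegP, a periplasmic protease and chaperone. The 36 libraries fall into 12 groups of 3 replicates. Wild-type cells were grown for 4 h and held for a further 0.5 h, either at 30 °C or at 42 °C throughout. Cells with a degP deletion were grown for 4 h at 30 °C and then held for 1 h at 30 °C or shifted for 1 h to 42 °C. The values analysed are the authors' deposited tables, 1 per regulator and condition. They give for each gene a mean normalised count, a log2 fold change of regulator over empty vector, its standard error (SE) and an adjusted p from 6 libraries. Counts per library were not analysed here, so that the spread between replicates enters through the authors' SE. The mean normalised counts summed to between 2940890 in the degP deletion at 30 °C and 19218367 in the wild type at 30 °C.

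The degP gene, which is absent from the deletion strains by design, had a mean normalised count of 0 in both of the authors' deposited tables for the degP deletion at 30 °C. After the shift to 42 °C the mean was 0.360 with FevRCit and 0.267 with FevREco105 in the authors' deposited tables. In wild-type cells it lay between 9545 and 9924 in the authors' deposited tables, so the tables match the genotypes in the labels. With wild-type cells at 30 °C degP was lower with either homolog, with log2 fold changes of -0.99 (SE 0.07) for FevRCit and -1.05 (SE 0.12) for FevREco105 in the authors' deposited tables. With growth at 42 °C it was higher with FevREco105 (0.84, SE 0.11), while with FevRCit it did not pass the test (0.19, SE 0.14), in the authors' deposited tables.

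Which genes responded to a regulator in every condition was asked first. With both homologs and in all 4 conditions, 12 genes rose and 21 fell at the authors' adjusted p under 0.05. The gene fkpA, which encodes a periplasmic peptidyl-prolyl isomerase with chaperone activity, rose with log2 fold changes from 1.52 (SE 0.15) to 2.53 (SE 0.14) in the authors' deposited tables. The other 11 that rose included ldcC, a lysine decarboxylase gene, its neighbours yaeR and tilS, the macroglobulin-like gene yfhM, and lrhA, which encodes a repressor of flagellar synthesis. The rest were the cell division gene ftsN, the periplasmic glucosidase gene bglX, and rhsA, rhsB, yabI and yhhT. In the authors' deposited tables ldcC lay between 1.42 (SE 0.10) and 2.63 (SE 0.12), yfhM between 0.85 (SE 0.10) and 2.60 (SE 0.13), and lrhA between 0.41 (SE 0.15) and 1.90 (SE 0.23). Of the 21 that fell, 13 belong to the list of flagellar and chemotaxis genes fixed before the data were examined, including flhD and flhC, whose products together activate the whole flagellar cascade. The flhD log2 fold change ran from -4.72 (SE 0.13) to -2.91 (SE 0.18) in the authors' deposited tables. The remaining 8 were the porin gene phoE, the periplasmic trehalase gene treA, the molybdate-responsive regulator modE, the lipopolysaccharide heptose gene gmhA, and dgcM, inaA, ygeV and yghB. In the authors' deposited tables phoE lay between -4.42 (SE 0.19) and -1.18 (SE 0.13). The slyX gene, which lies beside fkpA and was chosen after its values were seen, rose in 7 of the 8 comparisons, and was at 0.80 (SE 0.45) without passing in the authors' deposited table for FevRCit in the degP deletion at 30 °C. Counted per homolog, 20 genes rose and 32 fell with FevRCit among 3425 tested in all 4 conditions, and 19 rose and 34 fell with FevREco105 among 3339. Independent calls in the 4 conditions would have given 0.162 and 0.264 genes for FevRCit and 0.384 and 0.719 for FevREco105. The rhsA and rhsB genes are near-identical copies in part, so their values may share reads and are uncertain. The yabI gene lies beside araC, and its mean normalised count was only 9.79 with FevRCit and 10.3 with FevREco105 in the authors' deposited tables for the wild type at 30 °C.

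**Figure D1:**
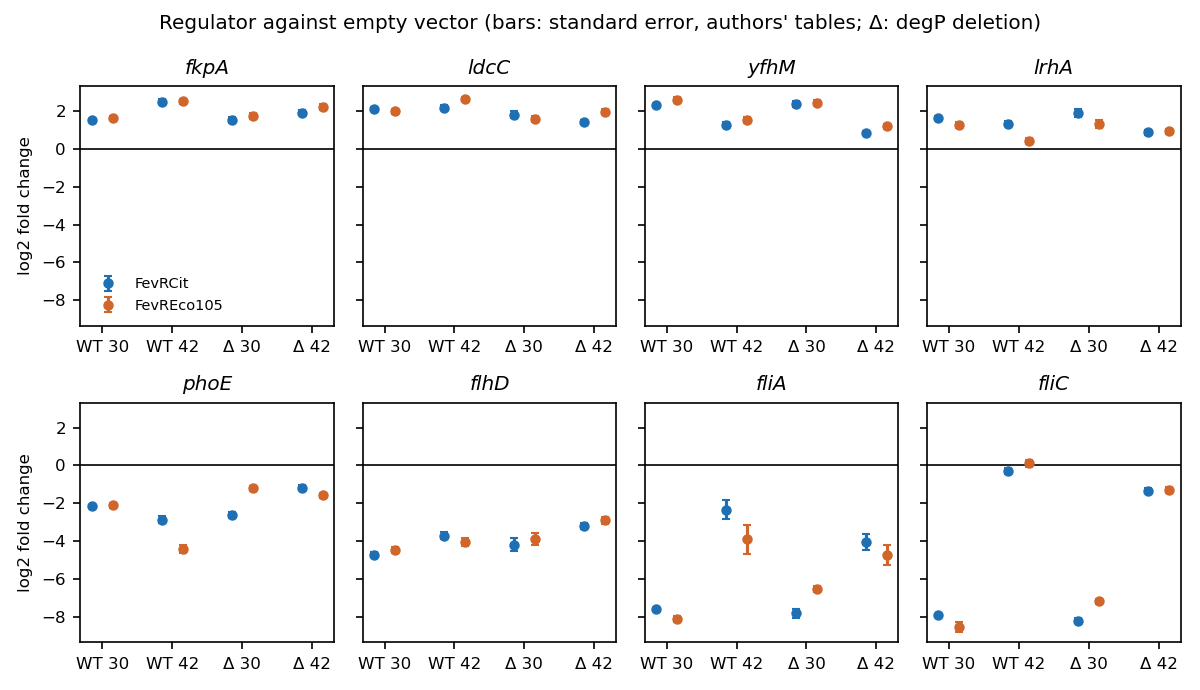
Log2 fold change of regulator over empty vector (y axis) for 8 genes in the wild type (WT) and the degP deletion (Δ) at 30 and 42 °C (x axis), from the authors' deposited tables, with their standard errors as bars. The genes fkpA, ldcC, yfhM and lrhA lie above 0 and phoE, flhD and fliA below 0 in all 8 comparisons, while fliC is near -8 at 30 °C and at -0.29 and 0.11 in the wild type grown at 42 °C.

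The number of genes called at the authors' adjusted p under 0.05 differed widely between comparisons. It was 1469 of 4254 genes tested with FevRCit and 773 of 4172 with FevREco105 in the wild type at 30 °C. Among genes with a mean of at least 20, the median SE there was 0.110 with FevRCit and 0.161 with FevREco105, so precision differed too. The test of the difference between homologs, given below, found 0 of 4172 genes there. The larger count therefore does not show that FevRCit changed more genes. Growth of the wild type at 42 °C gave 253 of 4145 and 1784 of 4228. Without degP it was 462 of 3521 and 916 of 3436 at 30 °C, and 997 of 4050 and 330 of 3884 after the shift to 42 °C. With a 2-fold minimum the counts for FevRCit and FevREco105 were 272 and 279, 64 and 652, 232 and 452, and 165 and 107, in the same order of conditions. The labels say only that the libraries are replicates, so these p-values measure the spread between the 3 libraries of each group.

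**Figure D2:**
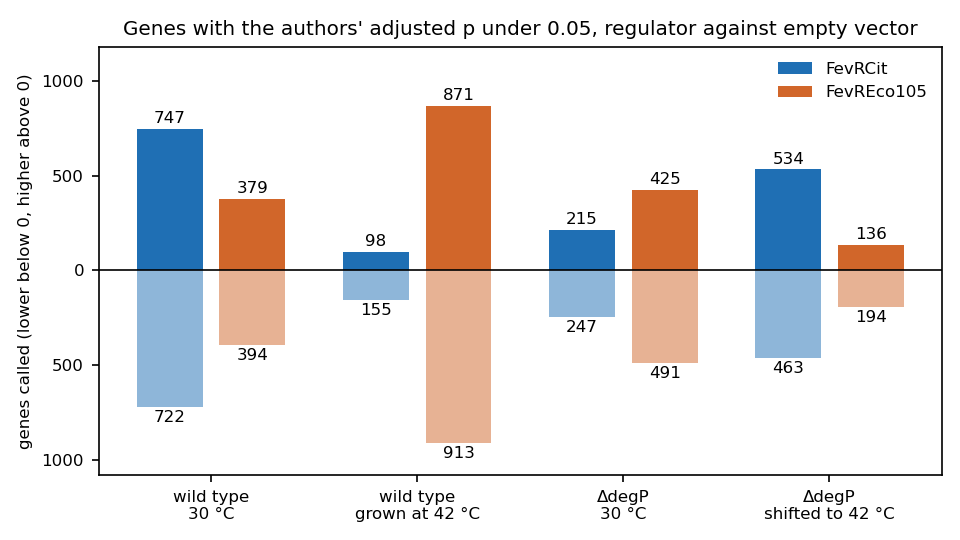
Number of genes (y axis) called higher (above 0) and lower (below 0) than the empty vector at the authors' adjusted p under 0.05, for FevRCit (blue) and FevREco105 (orange) in 4 conditions (x axis). The fewest calls are those of FevRCit in the wild type grown at 42 °C, 98 higher and 155 lower, and the most are those of FevREco105 in the same condition, 871 higher and 913 lower.

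At 30 °C in wild-type cells, flagellar genes were lower and heat shock chaperone genes higher with either homolog than with the empty vector. All 51 measured genes of the flagellar and chemotaxis list fell with each homolog, by medians of -7.08 for FevRCit and -7.52 for FevREco105 on the log2 scale. The flagellin gene fliC was at -7.94 (SE 0.06) and -8.55 (SE 0.24) in the authors' deposited tables, and the chemoreceptor genes tar and tsr, the chemotaxis genes cheA and cheW, the flagellar sigma factor gene fliA and the cyclic-di-GMP phosphodiesterase gene pdeH were all lower than -7 in both of the authors' deposited tables. Of 22 genes for chaperones and proteases controlled by sigma 32, 17 rose with FevRCit and 17 with FevREco105, including dnaK at 1.91 (SE 0.07) and 2.21 (SE 0.16), clpB at 2.02 (SE 0.07) and 2.11 (SE 0.14) in the authors' deposited tables. The small heat shock protein gene ibpA was at 2.46 (SE 0.09) and 3.08 (SE 0.24) in the authors' deposited tables. Adjusted over the list alone, 17 and 19 rose. Cysteine and sulfate assimilation genes rose in 15 of 26 cases with FevRCit and 10 of 26 with FevREco105, among them the sulfite reductase gene cysJ at 1.49 (SE 0.08) and 1.30 (SE 0.16) in the authors' deposited tables. Adjusted over the list alone, 16 rose and 1 fell with FevRCit and 10 rose with FevREco105. The largest increases outside these lists included csiE at 3.17 (SE 0.10) and 2.87 (SE 0.18), ydcH at 3.06 (SE 0.08) and 2.74 (SE 0.16), and the adjacent genes ygcN, ygcO and ygcP, with ygcN at 3.02 (SE 0.11) and 2.88 (SE 0.17) in the authors' deposited tables. The gene csrC, for a regulatory RNA, was at 2.77 (SE 0.33) and 3.10 (SE 0.48) in the authors' deposited tables. Genes with lower expression also included most of the sigma E envelope stress regulon, 24 of 32 with FevRCit and 17 of 32 with FevREco105, and 35 of 46 Fur-regulated iron uptake genes with FevRCit. The Fur decrease was not seen with FevREco105. Over the 45 Fur genes tested at both temperatures, the medians at 30 °C were -0.61 with FevRCit and 0.0037 with FevREco105. With limma's cameraPR test on the authors' Wald statistics, the flagellar list passed for both homologs, as did the sigma 32 list (adjusted p = 3.19e-11 for FevRCit and 1.94e-08 for FevREco105) and, for FevRCit, the cysteine list (adjusted p = 0.000983). The sigma E and Fur lists did not pass with FevRCit (adjusted p = 0.115 and 0.0546) unless the flagellar genes were left out (adjusted p = 1.52e-05 and 5.92e-07) or ranks were used (1.62e-07 and 2.68e-10). With FevREco105 the sigma E list did not pass either (adjusted p = 0.303), unless the flagellar genes were left out (0.000342) or ranks were used (7.51e-06). These 9 libraries were prepared and sequenced by another provider than the rest, per the labels, and 5S ribosomal RNA genes such as rrfB, which rose here, are near-identical copies left after depletion and are uncertain.

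Wild-type cells grown at 42 °C had the most genes that differed between homologs, by the test given below. In simulation that test recovered 80% of differences of 1 on the log2 scale there, and 26% in the degP deletion at 30 °C. The counts alone therefore do not rank the conditions. With FevRCit few genes changed strongly. In the authors' deposited table fkpA at 2.50 (SE 0.12), ldcC at 2.19 (SE 0.11), rhsB at 1.91 (SE 0.13) and csrC at 1.99 (SE 0.20) rose. The genes flhD at -3.71 (SE 0.18), phoE at -2.87 (SE 0.18) and ymgG at -2.46 (SE 0.18) fell in it. Of the 51 flagellar genes 14 fell with FevRCit, or 17 adjusted over the list alone, and fliC was at -0.29 (SE 0.17) without passing the test in the authors' deposited table. Pyrimidine synthesis genes rose in 4 of 13 cases (6 adjusted over the list alone), such as carA at 1.56 (SE 0.21), and RpoS stress genes fell in 6 of 28 (14 adjusted over the list alone, with 1 higher), such as osmY at -0.88 (SE 0.15) in the authors' deposited table. With cameraPR the flagellar list (adjusted p = 6.44e-17), the pyrimidine list (8.59e-05) and the RpoS list (0.000815) passed. The osmotic response list (0.00422), the Rcs list (0.0277) and the outer membrane protein list (0.0416) passed too, but not with an inter-gene correlation of 0.05 (adjusted p = 0.0560, 0.179 and 0.179), and the last 2 did not pass in the rank-based test either (0.582 and 0.374).

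With FevREco105 in the same condition, fatty acid degradation and RpoS stress genes rose, and ribosomal protein and anaerobic respiration genes fell. Fatty acid degradation genes rose in 9 of 10 cases, with 1 lower, led by fadB at 3.57 (SE 0.22) in the authors' deposited table. The arginine succinyltransferase pathway genes astE at 3.48 (SE 0.26) and astC at 3.09 (SE 0.21), the carbamoyl phosphate synthesis gene carA at 3.55 (SE 0.20) and the sialic acid pathway gene nanY at 3.11 (SE 0.21) rose in the authors' deposited table. Of 28 RpoS stress genes 22 rose, including blc at 1.56 (SE 0.16) in the authors' deposited table. Of the Fur-regulated genes 35 of 46 rose and 2 fell, with sufD at 1.26 (SE 0.16) and the ferrous iron transport gene feoA at -1.46 (SE 0.22) in the authors' deposited table. Envelope stress lists rose as well, 16 of 32 sigma E genes with 3 lower, 9 of 20 Cpx genes and 7 of 8 Bae genes. Examples are rpoE itself at 1.14 (SE 0.16), the periplasmic Cpx inhibitor gene cpxP at 1.17 (SE 0.15) and mdtC at 0.93 (SE 0.15) in the authors' deposited table. Ribosomal protein genes fell in 46 of 54 cases, with rplK at -1.22 (SE 0.12) in the authors' deposited table. Anaerobic respiration genes fell in 30 of 39, with the nitrate reductase gene narG at -4.09 (SE 0.53) and the formate dehydrogenase gene fdnG at -4.35 (SE 0.46) in the authors' deposited table. The porin gene ompF fell to -2.46 (SE 0.17), and adiY, an activator of arginine decarboxylase, to -4.94 (SE 0.56), the lowest in the authors' deposited table among genes named by the rule. Adjusted over the list alone, 25 RpoS, 35 Fur, 16 sigma E, 9 Cpx, 7 Bae and 9 fatty acid degradation genes rose, and 50 ribosomal and 31 anaerobic respiration genes fell. By cameraPR 21 lists passed, the strongest being ribosomal proteins (adjusted p = 3.96e-15), anaerobic respiration (1.60e-08), RpoS (1.86e-08) and fatty acid degradation (5.48e-08). The sigma E, Cpx, Bae and Fur lists passed at adjusted p = 0.00181, 0.00726, 0.00556 and 7.07e-07. Periplasmic chaperone and protease genes (adjusted p = 0.00198), arginine synthesis genes (0.00155), pyrimidine synthesis genes (5.04e-05), osmotic response genes (6.74e-05) and the lac operon (0.00603) also passed as higher. Purine synthesis genes (adjusted p = 0.000466), cold shock genes (0.00547), outer membrane protein genes (1.65e-05) and PhoP and PmrA regulated genes (0.00581) passed as lower. The flagellar, acid resistance, tricarboxylic acid cycle and cysteine lists (adjusted p = 0.00382, 0.0148, 0.00708 and 0.0343) lost their call with an inter-gene correlation of 0.05 (adjusted p = 0.0677, 0.0606, 0.0807 and 0.141). The lac operon and cysteine lists lost it in the rank-based test (adjusted p = 0.0774 and 0.0896).

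Without degP at 30 °C, flagellar genes again fell with both homologs, and the sulfur assimilation genes rose more than any other list with FevRCit. All 51 flagellar genes fell with each homolog, by medians of -6.95 and -5.97, and fliC was at -8.21 (SE 0.14) with FevRCit and -7.18 (SE 0.13) with FevREco105 in the authors' deposited tables. Cysteine and sulfate genes rose in 13 of 26 cases with FevRCit and 11 of 26 with FevREco105, with 1 lower in each; adjusted over the list alone, 15 and 14 rose. Examples with FevRCit are the thiosulfate uptake gene tsuA at 3.22 (SE 0.26), the sulfate binding protein gene sbp at 3.61 (SE 0.30) and cysJ at 3.12 (SE 0.20) in the authors' deposited table. Ribosomal protein genes rose in 20 of 54 cases with FevRCit and 53 of 54 with FevREco105, or 29 and 54 adjusted over the list alone, with rpsJ at 0.30 (SE 0.15, not passing) and 1.00 (SE 0.15) in the authors' deposited tables. Further groups changed with FevREco105. Sigma 32 genes rose in 19 of 22 cases, with 1 lower, including dnaK at 2.01 (SE 0.13) and ibpA at 3.66 (SE 0.29), and tricarboxylic acid cycle and aerobic respiration genes in 37 of 40, including sdhB at 1.88 (SE 0.14) in the authors' deposited table. The lactate and proline use genes lldP at 3.47 (SE 0.17) and putA at 3.31 (SE 0.17) were among the largest increases, and anaerobic respiration genes fell in 33 of 39 cases, with narG at -3.19 (SE 0.13) in the authors' deposited table. Adjusted over the list alone, 20 sigma 32 genes and 38 aerobic respiration genes rose and 33 anaerobic respiration genes fell. The phosphate regulon list rose in 21 of 29 cases, or 21 adjusted over the list alone, and the sugar uptake list, with malE at -1.28 (SE 0.12), fell in 26 of 65, or 29 adjusted over the list alone, in the authors' deposited table. With cameraPR the flagellar and cysteine lists passed for both homologs (cysteine adjusted p = 1.19e-16 and 0.000721). For FevREco105 so did anaerobic (9.16e-20) and aerobic respiration (6.53e-16), sigma 32 (3.44e-11), ribosomal proteins (1.81e-10) and the phosphate regulon (0.000890). The ribosomal list with FevRCit (adjusted p = 0.00131) and the RpoS and sugar lists with FevREco105 (0.0207 and 0.00559), all passing, did not pass with an inter-gene correlation of 0.05 (adjusted p = 0.141, 0.164 and 0.164). This condition had the lowest summed mean normalised counts, and the 5S ribosomal RNA gene rrfG, at the top of both lists of increases, is a near-identical copy and uncertain.

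After cells without degP were shifted to 42 °C, acid resistance genes and the remaining flagellar expression fell with both homologs. The glutamate-dependent acid resistance list fell in 16 of 16 cases with FevRCit and 13 of 16 with FevREco105, or 16 and 14 adjusted over the list alone. The periplasmic acid chaperone gene hdeA was at -3.30 (SE 0.39) and -2.59 (SE 0.45), and the glutamate decarboxylase gene gadB at -2.33 (SE 0.35) and -2.25 (SE 0.20) in the authors' deposited tables. Flagellar genes fell in 39 and 32 of 51 cases, or 41 and 42 adjusted over the list alone, with medians of -1.64 and -1.60. The maltose genes lamB at -2.72 (SE 0.13) and -1.50 (SE 0.14) and malE at -2.34 (SE 0.12) and -1.29 (SE 0.16) fell with both in the authors' deposited tables. The phage shock list rose in 6 of 7 cases with FevRCit and 3 of 7 with FevREco105, such as pspE at 0.62 (SE 0.11) and 0.49 (SE 0.17) in the authors' deposited tables. With FevRCit 51 of 54 ribosomal protein genes and 14 of 26 cysteine and sulfate genes rose. With it 21 of 28 RpoS genes fell, with osmY at -1.17 (SE 0.13) in the authors' deposited table. With FevREco105 the sigma 32 list instead fell in 7 of 22 cases, with groL at -1.04 (SE 0.15) and dnaK at -0.79 (SE 0.14) in the authors' deposited table. Adjusted over the list alone, 7 phage shock, 53 ribosomal and 14 cysteine genes rose and 21 RpoS genes fell with FevRCit. By the same adjustment 6 phage shock genes rose and 8 sigma 32 genes fell with FevREco105. With cameraPR the acid resistance list (adjusted p = 5.22e-23 and 9.18e-27), the flagellar list (1.37e-38 and 7.35e-64) and the ribosomal list (5.22e-23 and 7.15e-05) passed for both homologs. So did the phage shock (0.00164 and 0.00179), sugar uptake (1.35e-07 and 3.15e-07) and pyrimidine lists (0.00253 and 0.00320). With FevRCit the cysteine (4.93e-09), RpoS (1.10e-14), anaerobic respiration (0.000106), purine (9.69e-07) and phosphate lists (0.000757) passed. With FevREco105 the sigma 32 and sigma E lists did (both adjusted p = 0.000932). They did not move alike, as the sigma 32 list fell and the sigma E members other than fkpA had a median of 0.159. The purine list and the outer membrane protein list with FevREco105 (adjusted p = 0.0159 and 0.0351) did not pass with an inter-gene correlation of 0.05 (0.0730 and 0.123). The latter did not pass in the rank-based test either (0.794), and for it the median of 0.02 and the mean of -0.24 differ in sign. Over all 8 comparisons 26 of the 37 lists passed at least once, and the other 11 had smallest adjusted p-values between 0.0580 and 0.936.

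**Figure D3:**
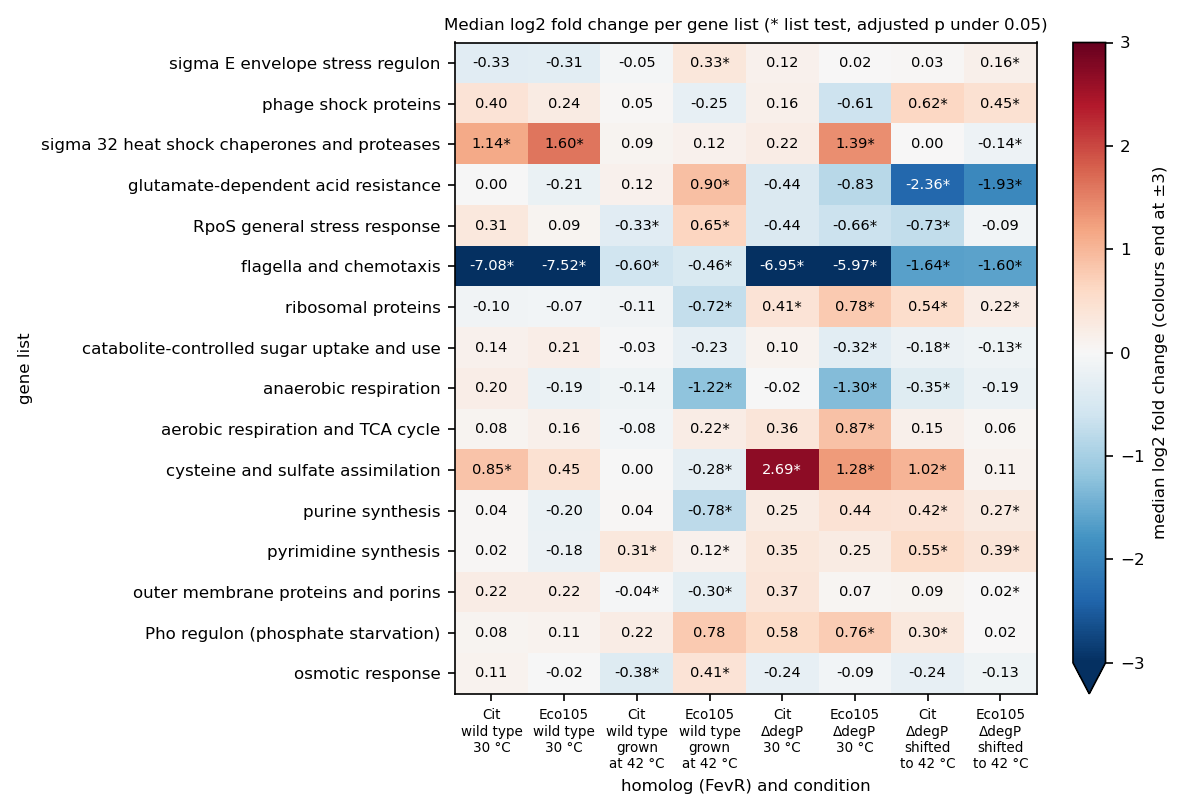
Median log2 fold change (colour and number) of the 16 gene lists that passed limma's cameraPR test in at least 2 comparisons (y axis), for each homolog and condition (x axis), from the authors' deposited tables; an asterisk marks adjusted p under 0.05. The flagellar list is lower in all 8 columns, and the sigma 32 list is at 1.14 and above in 3 of the 4 columns at 30 °C.

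How alike the homologs were was tested by the difference of their log2 fold changes within a condition. The genes fkpA, ldcC, lrhA, flhD and phoE had differences between -0.24 and 0.40 in the wild type at 30 °C, where 0 of 4172 genes passed. The test was a normal test on the authors' fold changes and SEs that counts the error of the shared empty-vector libraries into both. At an unadjusted p under 0.05 there were 284 genes, where 208.6 would be expected by chance if the error were not too large. With the shared error taken out 170 genes passed after adjustment. List tests did pass there, but cameraPR takes the genes of a list as its units, with a preset correlation. Its p-values, here and in the other conditions, do not measure the spread between the 3 libraries of a group. The flagellar list is also compared at residual levels, 0.0575% of implied counts with FevRCit and 0.0420% with FevREco105. With cameraPR on the statistics of the difference 18 of 37 lists passed, the strongest being the flagellar (median difference 0.46, adjusted p = 9.35e-19), Fur (-0.46, 7.11e-18), anaerobic respiration (0.43, 2.16e-16), sigma 32 (-0.30, 1.46e-11) and RpoS lists (0.21, 1.75e-05). Of the 18, 10 passed with an inter-gene correlation of 0.05, these 5 among them. Growth of the wild type at 42 °C gave 1111 of 4144 genes that differed. Among them adiY 4.22 (SE 0.64), narK 3.90 (SE 0.75) and fdnG 3.43 (SE 0.50) were higher with FevRCit, and fadB -3.84 (SE 0.29), astA -3.41 (SE 0.30) and nanY -2.98 (SE 0.36) were higher with FevREco105. There the lrhA increase was larger with FevRCit by 0.93 (SE 0.19) and the phoE decrease larger with FevREco105, by 1.54 (SE 0.27), while fkpA differed by -0.02 (SE 0.18). The ldcC increase was larger with FevREco105 by 0.44 (SE 0.16, adjusted p = 0.0292). Of 36 lists 20 differed, such as ribosomal proteins (0.74, adjusted p = 4.29e-16), RpoS (-0.99, 1.95e-15) and fatty acid degradation (-1.33, 2.92e-12), and 11 did with a correlation of 0.05, these 3 among them. Without degP at 30 °C, 300 of 3421 genes differed. These included the threonine degradation gene tdcE at 3.67 (SE 0.27) and the lysine decarboxylase gene cadA at 3.45 (SE 0.43), higher with FevRCit, and putA at -3.81 (SE 0.28) and lldP at -3.82 (SE 0.30), higher with FevREco105. There the phoE decrease was larger with FevRCit, by 1.40 (SE 0.22, adjusted p = 3.56e-09). Of 35 lists 10 differed, such as anaerobic (1.48, adjusted p = 2.22e-39) and aerobic respiration (-0.43, 3.71e-28) and sigma 32 (-1.16, 7.15e-19). After the shift to 42 °C, 132 of 3881 genes differed, led by the asparagine synthetase gene asnA at 2.92 (SE 0.18), which was at 0.51 (SE 0.14) with FevRCit and -2.42 (SE 0.13) with FevREco105 in the authors' deposited tables. The sulfate activation gene cysD differed by 1.91 (SE 0.52) there, and ilvX by -2.48 (SE 0.72). The ldcC increase was larger with FevREco105 by 0.56 (SE 0.17, adjusted p = 0.0286). Of 36 lists 12 differed, such as RpoS (-0.63, adjusted p = 4.49e-18), ribosomal proteins (0.31, 4.07e-12) and cysteine (1.04, 1.39e-08), and 5 did with a correlation of 0.05, these 3 among them.

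The 2 homologs called 680 genes the same way and 0 in opposite ways in the wild type at 30 °C, 162 and 32 in the wild type grown at 42 °C, 333 and 35 in the degP deletion at 30 °C, and 223 and 5 after the shift. Independent lists would have shared 67.9 higher and 68.2 lower genes in the wild type at 30 °C, where 321 and 359 were shared. The corresponding values were 20.6 and 34.1 against 61 and 101 in the wild type grown at 42 °C, 26.5 and 35.5 against 135 and 198 in the degP deletion at 30 °C, and 18.7 and 23.0 against 86 and 137 after the shift. Both lists of a condition rest on the same empty-vector libraries, so they are not independent and this reference can be too low. The covariance of the fold changes across genes, which are not independent replicates, was 1.02, 0.129, 1.07 and 0.186 in this order of conditions, against simulated values of 0.0215, 0.0287, 0.0657 and 0.0237. Without the flagellar genes it was 0.364, 0.107, 0.436 and 0.119. The Pearson correlation across genes was 0.966, 0.423, 0.838 and 0.747, and 0.482 to 0.504 in the simulation. In the wild type grown at 42 °C it lay below the simulated 0.502. The simulated groups hold no changed genes, and changes with 1 homolog alone can lower a correlation. The correlation there therefore does not decide whether the homologs were alike. The 3 empty-vector libraries of a condition could not be split. Part of the excess of the shared calls and of the covariances may therefore come from these shared controls. The same holds for the correlations in the other conditions.

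**Figure D4:**
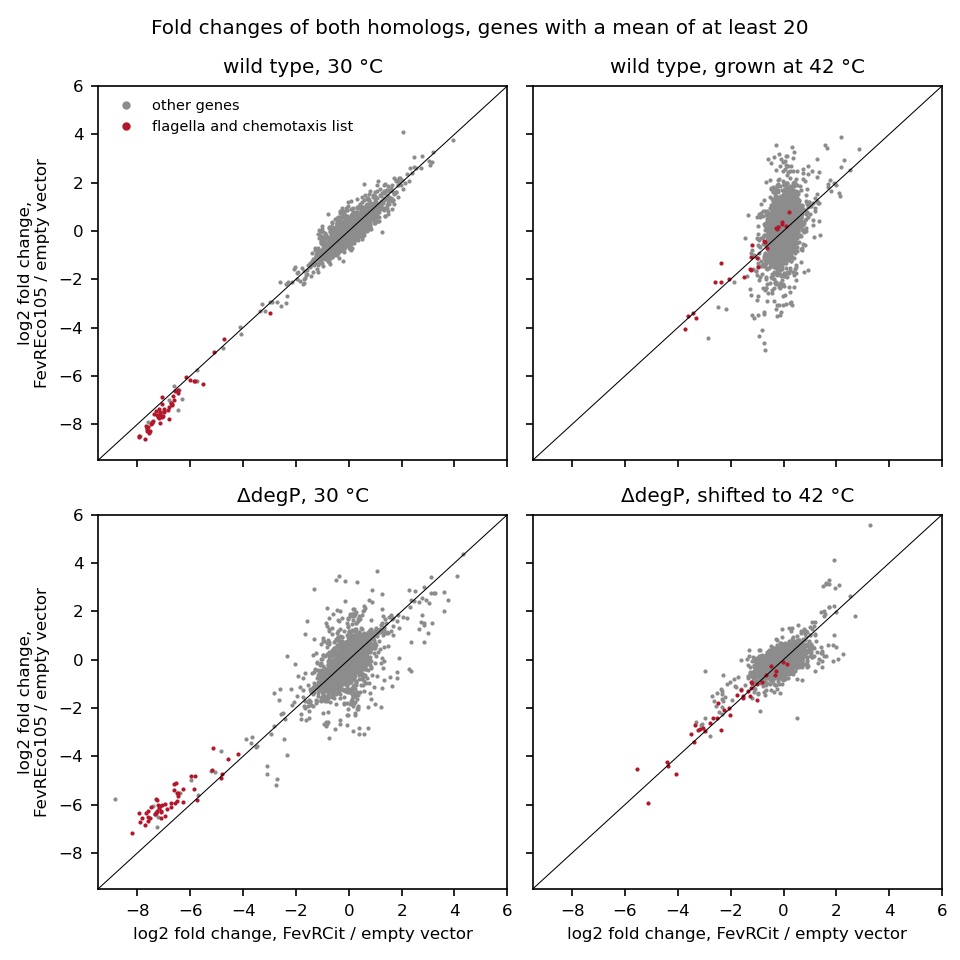
Log2 fold change over the empty vector with FevRCit (x axis) and FevREco105 (y axis) of genes with a mean of at least 20 in both tables, from the authors' deposited tables, per condition; red points are the flagellar and chemotaxis list and the line marks equal values. The points lie along the line in the wild type at 30 °C (Pearson correlation 0.966) and spread along the y axis in the wild type grown at 42 °C (0.423).

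Whether an effect depended on temperature was tested by the difference between the fold changes at 42 and 30 °C. Flagellar and chemotaxis genes fell less at 42 °C: 48 of 48 tested list members with FevRCit and 50 of 51 with FevREco105 differed in the wild type, and 47 of 49 and 43 of 46 in the degP deletion. At 30 °C the flagellar list made up 9.89% of all normalised counts in the wild-type empty vector and 10.6% in that of the degP deletion, as implied by the authors' deposited tables. At 42 °C the shares were 0.0712% and 0.106%. These levels come from tables normalised separately, and no test was run between them. The sigma 32 genes rose less at 42 °C in the wild type, in 16 of 22 cases with FevRCit and 15 of 22 with FevREco105, where 1 rose more. Of these genes, dnaK made up 0.346% of implied counts in the wild-type empty vector at 42 °C and 0.167% at 30 °C. Such shares are not given for the other members. Whether a higher starting level gave the smaller increases was not tested. The increase of csiE at 30 °C gave way in the wild type to decreases at 42 °C of -1.14 (SE 0.12) and -0.98 (SE 0.14) in the authors' deposited tables. The fkpA increase in the wild type was larger at 42 °C by 0.97 (SE 0.14) with FevRCit and 0.88 (SE 0.16) with FevREco105, while in the degP deletion the differences of 0.41 (SE 0.19) and 0.46 (SE 0.22) did not pass. In all, 558 and 1477 genes differed between temperatures in the wild type with FevRCit and FevREco105, and 249 and 571 in the degP deletion. Temperature coincides with the provider that made the libraries in the wild type, and their effects cannot be told apart there. Direct comparisons of the empty-vector groups between temperatures were not run, because the tables give no shared scale.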

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

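The tests of explanations below, and the tests of differences between temperatures with list tests on them, were chosen after the results were seen.

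The effect of a regulator differed between 42 and 30 °C by a test of the difference itself, and this is what set the following results apart. In the degP deletion 249 genes differed with FevRCit and 571 with FevREco105, and in the wild type 558 and 1477. In the wild type the libraries at 30 °C came from another provider, so temperature and provider cannot be told apart there. In the degP deletion the labels name no such split. The positive differences below include many flagellar and chemotaxis genes, whose expression was already low in the empty vector at 42 °C. The flagellar list made up 0.0712% of its implied counts in the wild type grown at 42 °C, against 9.89% at 30 °C. After the shift of the degP deletion it was 0.106%, against 10.6%. Little was thus left to fall at 42 °C, and whether this gave the differences was not tested.

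In the degP deletion with FevRCit the fold change at 42 °C minus that at 30 °C was 8.58 for ymdA (SE 1.58, on a mean normalised count of only 71.3 in the authors' deposited table at 30 °C), 7.58 for the chemoreceptor gene trg, 7.31 for rdcB, 7.18 for tsr and 6.93 for cheW. It was -3.54 for slp, -3.44 for the acid resistance gene hdeD, -3.29 for ydcH, -3.11 for csiE and -3.03 for the glutaminase gene glsA. With FevREco105 it was 6.59 for trg, 6.43 for rdcB, 6.23 for the flagellar brake gene ycgR, 6.07 for flgL and 5.94 for tar. The small heat shock protein genes ibpA and ibpB were at -4.22 and -4.21, the lactate genes lldP and lldR at -3.65 and -3.21, and ygcN at -3.15.

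In the wild type with FevRCit the same difference was 8.14 for pdeH, 7.79 for cheY, 7.67 for tar, 7.65 for fliC and 7.60 for ycgR, and -4.30 for csiE, -3.05 for ygcO, -2.91 for ygcN, -2.78 for yjfN and -2.70 for ydcH. With FevREco105 it was 8.65 for fliC, 8.48 for tsr, 8.45 for pdeH, 8.39 for cheY and 8.19 for tap, and -5.27 for adiY, -4.32 for narK, -3.99 for ygcO, -3.85 for csiE and -3.81 for napF. Of the single genes given here, ymdA had the largest SE and the others SEs of at most 0.94.

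Of the gene lists, those that differed the same way with both homologs are given as medians of the difference, FevRCit first. In the wild type they were 6.14 and 6.95 for the flagellar list, 0.64 and 1.47 for the Fur list, 0.34 and 0.68 for the sigma E list, -0.86 and -1.24 for the sigma 32 list, -0.85 and -1.04 for the cysteine list and -0.29 and -0.54 for the outer membrane protein list. The Fur list with FevRCit did not pass with an inter-gene correlation of 0.05 (adjusted p = 0.284). In the degP deletion they were 4.50 and 3.90 for the flagellar list and -1.30 and -1.13 for the cysteine list.

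The pattern weighed here is the lower flagellar expression with each regulator at 30 °C. A factor per library moves all genes alike, so the authors' normalization would not set the flagellar list apart from the other genes. The median of the flagellar list lay at least 6.015 on the log2 scale from that of the other genes in the 4 comparisons at 30 °C. This distance restates the pattern, so it is not a separate test of the normalization. The fold changes of the other genes had standard deviations of at most 0.857. A difference between separately made strains was not tested and stays open, because each plasmid was carried by 1 strain per background. The increase of lrhA, whose product represses flhDC, could be the route. The homolog with the larger lrhA increase had the larger flhD decrease in 2 of 4 conditions, which were both of those at 30 °C. The flhD difference between homologs passed in none of the 4 (smallest adjusted p = 0.382), so this order decides nothing. In the wild type grown at 42 °C lrhA was at 1.34 with FevRCit and 0.41 with FevREco105, a difference of 0.93 (SE 0.19). There flhD was at -3.71 and -4.07, so the larger lrhA increase did not go with a larger flhD decrease. That is 1 condition and not at 30 °C, so the lrhA explanation stays open for the pattern weighed here. A direct effect of the regulators was not tested.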

How the results depend on the processing

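The settings named recentring, a mean of at least 20, shared-control variance, rank-based lists, correlation of 0.05 and flagellar genes left out, and the tests of differences and lists themselves, were chosen after the data were seen. Of the 279 results for named genes with a regulator, all kept their direction and call with no low-count filter and after recentring on the median fold change, and 276 did at adjusted p under 0.01. The 3 that did not were ytiD with FevRCit in the wild type grown at 42 °C, rrfG with FevRCit in the degP deletion at 30 °C and rrfB with FevREco105 after the shift. Of the 65 list calls, 53 were kept with a correlation of 0.05, 60 in the rank-based test, which added 49, and all 57 that did not concern the flagellar list with the flagellar genes left out, which added 8. Of the 99 list calls on differences, 67 were kept with a correlation of 0.05 and 93 in the rank-based test, which added 35.

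Requiring a 2-fold change, which shortens any such count by construction, left 272 and 279 genes for FevRCit and FevREco105 in the wild type at 30 °C, 64 and 652 grown at 42 °C, 232 and 452 in the degP deletion at 30 °C and 165 and 107 after the shift. It left 453 and 43 genes that differed between homologs in the wild type grown at 42 °C and after the shift. It left 342 that differed between temperatures with FevREco105 in the degP deletion, and 223 and 766 with FevRCit and FevREco105 in the wild type. It left 20 and 26 genes in all 4 conditions for the 2 homologs, and 210, 46, 179 and 74 genes shared by both homologs in the wild type at 30 and 42 °C and the degP deletion at 30 and 42 °C. At adjusted p under 0.01 the counts were 162 for FevRCit in the wild type grown at 42 °C and 211 for FevREco105 after the shift, and 720 and 80 for the homolog difference in these conditions. With the shared-control variance removed, 170, 1750, 525 and 507 genes differed between homologs in the 4 conditions, in the same order. The rank-based list test gave 12 and 12 lists in the wild type at 30 °C and 16 and 15 in the degP deletion at 30 °C, and the cause was not tested. A correlation of 0.05 left 3 lists for FevRCit in the wild type grown at 42 °C. A correlation of 0.05 left 10, 11 and 5 lists that differed between homologs in the wild type at 30 and 42 °C and after the shift, from 18, 20 and 12. The rank-based test gave 16 in the degP deletion at 30 °C, from 10, and for the differences between temperatures 12 and 15 in the degP deletion, from 6 and 9, and 14 with FevRCit in the wild type, from 7.

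No named gene or list that kept its call changed direction, but the balance of higher and lower genes turned in 8 counts, 1 of them under 2 settings. At 2-fold it went from 747 and 722 to 116 and 156 for FevRCit in the wild type at 30 °C, from 98 and 155 to 33 and 31 grown at 42 °C, and from 534 and 463 to 43 and 122 after the shift. It went from 871 and 913 to 331 and 321 for FevREco105 in the wild type grown at 42 °C. For the homolog difference it went from 588 and 523 to 207 and 246 in that condition and from 159 and 141 to 105 and 107 in the degP deletion at 30 °C. For the difference between temperatures in the wild type it went from 270 and 288 to 132 and 91 with FevRCit. With FevREco105 it went from 743 and 734 to 537 and 552 at adjusted p under 0.01, and to 739 and 742 after recentring.

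No paired analysis was possible because the tables hold no values per library. For the same reason leaving out replicates, a replicate block, other splits of the samples, another tool or normalization on counts, other samples in the fit, pseudocounts, estimated correlation and the tests between the empty-vector groups were not run. In the simulated stand-in for the test against the empty vector, changes of 1 on the log2 scale were recovered least in the degP deletion at 30 °C, in 52.0% of genes. The lowest summed means and the highest median implied dispersions (0.0487 and 0.0419) both occurred there, and their parts were not separated.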

Other observations

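The list tests in this part were chosen after the results were seen, and no explanation was tested.

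The increase of fkpA stood apart from the rest of its regulon. Of the sigma E list, fkpA had the highest fold change in 8 of 8 comparisons, but it was chosen for this increase, so the rank is a description and not a test. The other members had medians between -0.34 and 0.32, and the next highest gene was at 0.11 for bamE with FevREco105 in the wild type at 30 °C and at most 1.72 for sbmA with FevREco105 in the wild type grown at 42 °C.

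Of the 12 genes that rose in all 8 comparisons, ldcC, yaeR and tilS lie side by side. The fold change fell in the order ldcC, yaeR, tilS in 8 of 8 comparisons. Whether they share a transcript was not tested.

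The ribosomal protein and RpoS lists both passed in 3 of 8 comparisons, each time with medians of opposite sign, but not always the same way round. With FevREco105 in the wild type grown at 42 °C the ribosomal median was -0.72 and the RpoS median 0.65. They were 0.78 and -0.66 with FevREco105 in the degP deletion at 30 °C, and 0.54 and -0.73 with FevRCit after the shift. The RpoS call of FevREco105 in the degP deletion at 30 °C was lost with an inter-gene correlation of 0.05 (adjusted p = 0.164). With FevRCit in the wild type grown at 42 °C both medians were negative, at -0.11 and -0.33. Growth phase at harvest was not tested, and the labels give no optical density.

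Reads of araC and yabI stood without those of their neighbours. In the 6 of the authors' deposited tables other than the wild type at 30 °C, the 7 genes beside them had means of at most 1.41, while araC and yabI had at least 49.4. In the authors' deposited tables for the wild type at 30 °C araC had a mean of 0, yabI 9.79 and 10.3, and the 7 genes 0. Whether the plasmid carries this region, and whether the strain lacks it, was not tested, and the fold changes of araC and yabI are uncertain for this reason.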
